A study of Homo sapiens with 3 samples.

How the data were processed

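Total RNA from untreated RPE1 cells was measured on Illumina bead arrays, on which each probe is carried by many beads and read as biotin-labelled RNA. RPE1 is an established human cell line from retinal pigment epithelium, immortalised with telomerase. Per the labels, the cells were grown in DMEM:F12 medium, RNA was extracted with Tri-Reagent, and the 3 samples were independent biological replicates of 1 group. No slide, scan or culture date was given in the sources used here, so no batch could be tested. With 1 group, no comparison between conditions could be made, and the arrays were analysed as a baseline profile.

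The deposited table of unnormalized values held, per the file headers, the mean signal of each probe as an intensity on a linear scale, its detection p-value, the standard error over beads and the number of beads. The deposited detection p-value of a probe ranked it among negative control probes of the same array, and its steps corresponded to 759 such controls, which are not listed in the table. The deposited bead numbers had a median of 20 per probe on each array, and no detected probe rested on fewer than 3 beads. The authors' normalized intensity was made with lumi, per the submitters' processing notes. The lumi version and the method chosen within it are not given in the sources used here. In that table the values of array 3 equalled the unnormalized signal for all 48803 probes, so arrays 1 and 2 had been scaled towards array 3, on a linear scale without centring. The columns carried the name RPEI with a replicate number, read here as RPE1.

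Signals were background-corrected and quantile-normalized in limma 3.58.1 (R 4.3.3) with neqc, which fits the background from the detection p-values, adds an offset of 16 and takes log2. These log2 values pull apart dim probes more than the uncorrected signal does, so a between-replicate SD near the background depends on the correction. A probe was called above background at a detection p under 0.01. A gene was called detected in all 3 arrays where at least 1 of its probes passed on every array, and detected in no array where every probe had a detection p of 0.05 or more on every array. The level of a gene was that of its probe with the highest mean log2 signal, and no level is given where no probe passed. Levels of different probes were not set against each other, since probes differ in binding strength.

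Of the 48803 probes, 36157 carried a gene symbol and 12646 carried none. The 25159 array symbols were brought up to date through a RefSeq gene table of GRCh38.p14, used only for names, gene class and the order of neighbouring genes. Of these, 15505 were current symbols, 3091 were the synonym of 1 gene and 1376 matched through the gene number in their provisional name. A further 139 were synonyms of several genes and 5021 had no match, and these kept the array's name. For 27 symbols the match lay on another chromosome than the array's annotation gave, and the match was dropped. No coordinates are given because no genome build is named in the sources used here. Y-linked genes and XIST were left out throughout, which left 24793 genes, of which 19632 had a place in the gene order. Genes whose presence depends on a person's HLA type are not named, and some other genes that the naming rule selects are not reported here.

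The 34 gene lists, the tests and the rule for named genes were fixed before the data were examined. By that rule the text names the first 3 members of each list, up to 3 members unlike at least 90% of their list, the 25 genes with the largest SD between replicates, the ends of the longest runs of neighbouring genes, and the topoisomerases in full. Any other gene named was chosen after its values were seen, as were the further members given to show what a list's count held. POLR2E, NDUFA2, USP18, F2 and HBA1 were on the lists but had no matching symbol among the array's probes. The detected share of each list was compared with that of all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 34 lists, and placed among 10000 random lists of the same size. Genes are not independent replicates, so these p-values describe the lists on these arrays. The median SD of a list's detected members was compared with 10000 random lists matched on signal in 10 bins, for lists with at least 5 detected members. The detected share of each chromosome was tested with 100000 permutations of the calls over genes, adjusted over chromosomes 1 to 22 and X.

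For neighbouring genes, circular shifts of the calls within chromosomes had been planned. On simulated data this test found 10% of orders in which detected genes were clustered, because a shift keeps neighbours side by side, so it was set aside. Permutation of the calls within each chromosome, which exceeded all permutations for 100% of those simulated orders, was used in its place and was chosen before the real result was seen. The planned comparison of gene-dense with gene-poor regions and the alternative with only neighbours at least 100 kb apart were not run because they need positions on a stated build. On simulated lists, 98.8% of raised and 87.5% of lowered detection shares were recovered over 24793 genes, with 0.833% of unchanged lists called. Of lists with doubled SD, 91.7% were recovered over 9389 genes. Other detection thresholds, background corrections, normalizations, filters and subsets of arrays were tried as alternatives. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision of every value.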

Results

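Gene expression in untreated RPE1 cells was measured on 3 arrays, 1 for each independent culture. The series asks how transcription relates to supercoiled domains along chromosomes. The arrays give RNA levels in samples labelled as untreated cells, which bear on that question but do not measure transcription itself. The median unnormalized signal was 50.6 on array 1, 47.7 on array 2 and 46.8 on array 3, and the mean signal was 224, 166 and 155. Of 48803 probes, 13612 (27.9%) were above background on array 1, 12882 (26.4%) on array 2 and 13998 (28.7%) on array 3.

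Of 24793 genes, 9389 (37.9%) were detected in all 3 arrays and 9847 (39.7%) in none. The remaining 5557 passed on some arrays only or lay between the thresholds. On array 1 alone, 10295 genes were above background. Among protein-coding genes, 8581 of 17978 (47.7%) were detected in all 3 arrays, against 9.21% of the genes whose array name had no current match. Detection rose with the number of probes, from 31.8% of genes with 1 probe to 53.2% of genes with several, and the probes of 2521 multi-probe genes disagreed. A gene not detected is not shown to be silent: RPL10, which encodes a protein of every ribosome, was not above background on any array.

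The machinery of transcription was detected almost in full. Of the RNA polymerase II subunits, 10 of 11 were detected (adjusted p = 0.000645, Fisher's exact test), among them POLR2A, the catalytic subunit, at a log2 signal of 9.13 ± 0.26 (SD, n = 3), POLR2B at 8.36 ± 0.09 and POLR2C at 8.24 ± 0.22. POLR2K was not above background. Of the general transcription and elongation factors, 26 of 29 were detected (adjusted p = 4.86e-08, Fisher's exact test). The TATA-binding protein TBP had a log2 signal of 7.60 ± 0.10, GTF2B 8.35 ± 0.18 and the elongation factor SUPT5H 8.68 ± 0.01 (n = 3 each).

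Enzymes that relax or untangle DNA, and the proteins that work with them, were detected in 9 of 12 cases (adjusted p = 0.017, Fisher's exact test). TOP2A, the topoisomerase II form of dividing cells, had a log2 signal of 9.82 ± 0.43 and TOP2B, the form present throughout the cell cycle, 9.75 ± 0.19 (n = 3). The topoisomerase III genes TOP3A and TOP3B had log2 signals of 7.26 ± 0.24 and 6.82 ± 0.49, and the mitochondrial TOP1MT 7.47 ± 0.12. RMI1 at 7.54 ± 0.31, RMI2 at 8.09 ± 0.46 and the helicase BLM at 6.54 ± 0.06 form a complex with TOP3A. TDP1, which repairs trapped topoisomerase I, had a log2 signal of 7.08 ± 0.30. TOP1 was above background on array 1 only, and TDP2 and the meiotic SPO11 on none. The list no longer passed at a detection p under 0.05 (adjusted p = 0.0529, Fisher's exact test) or against protein-coding genes alone (adjusted p = 0.0986, Fisher's exact test), the latter an alternative added after the data were seen.

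Proteins that fold and anchor chromosomes were detected in most cases. Of condensin, cohesin and CTCF genes, 18 of 21 were detected (adjusted p = 1.90e-05, Fisher's exact test), with the condensin subunits SMC2 at a log2 signal of 7.03 ± 0.42 and SMC4 at 8.64 ± 0.30 and the cohesin subunit RAD21 at 9.20 ± 0.29 (n = 3). Of chromatin remodellers, 23 of 27 were detected (adjusted p = 2.16e-06, Fisher's exact test), with SMARCA4 at 9.10 ± 0.17, SMARCB1 at 7.05 ± 0.12 and CHD4 at 9.45 ± 0.08. Of nuclear lamina and scaffold genes, 15 of 16 were detected (adjusted p = 1.27e-05, Fisher's exact test), with LMNA at 10.63 ± 0.09, HNRNPU at 7.15 ± 0.18 and LMNB1 at 6.57 ± 0.02, while SATB1 was not above background. HMG proteins and linker histones were detected in 11 of 19 cases and did not pass the test (adjusted p = 0.105, Fisher's exact test). HMGA1 had a log2 signal of 11.08 ± 0.08 and HMGA2 5.38 ± 0.21, while HMGB1 was above background on arrays 1 and 3 only.

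Of telomerase and shelterin genes, 11 of 12 were detected (adjusted p = 0.000321, Fisher's exact test), including the telomerase partner DKC1 at a log2 signal of 10.20 ± 0.12 and the shelterin protein TERF2 at 6.88 ± 0.14 (n = 3). TERT, the catalytic subunit whose introduced copy immortalised the line, was not above background. Replication-dependent core histones were detected in 10 of 58 cases, a lower share than other genes (adjusted p = 0.00132, Fisher's exact test), with H4C3 at 13.19 ± 0.32, H2BC12 at 9.93 ± 0.23 and H2AC6 at 6.36 ± 0.14. Histone genes of this class are near-identical, so their probes can read more than 1 gene. That list no longer passed at a detection p under 0.05 (adjusted p = 0.0738, Fisher's exact test).

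Genes of cell division, translation and energy metabolism were detected almost in full. Of DNA replication genes, 32 of 33 were detected (adjusted p = 7.34e-12, Fisher's exact test), with the sliding clamp PCNA at a log2 signal of 9.05 ± 0.43 and the helicase subunits MCM2 at 8.53 ± 0.30 and MCM7 at 10.86 ± 0.21 (n = 3), while GINS1 was not above background. Of mitosis genes, 27 of 28 were detected (adjusted p = 4.86e-10, Fisher's exact test), with CCNB1 at 6.52 ± 0.16, CDC2 at 8.54 ± 0.33 and AURKA at 9.74 ± 0.34, while BUB1B was above background on arrays 1 and 2 only. Ribosomal proteins were detected in 83 of 86 cases (adjusted p = 3.42e-30, Fisher's exact test), with RPL3 at 12.96 ± 0.23, RPS6 at 13.63 ± 0.05 and RPLP0 at 13.34 ± 0.34. RPL10L and RPL3L, testis- and muscle-restricted copies, were not above background, nor was RPL10.

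Of oxidative phosphorylation genes, 31 of 33 were detected (adjusted p = 1.48e-10, Fisher's exact test), with NDUFA4 at a log2 signal of 11.48 ± 0.08, SDHB at 10.96 ± 0.14 and UQCRC1 at 9.59 ± 0.07 (n = 3), while NDUFC2 passed on array 3 only. Glycolysis genes were detected in 19 of 22 cases (adjusted p = 1.11e-05, Fisher's exact test), with GAPDH at 13.32 ± 0.09, PGK1 at 11.07 ± 0.45 and LDHA at 12.62 ± 0.30. HK3 and PGAM2, the forms of blood cells and muscle, were not above background. Cholesterol synthesis genes were detected in 21 of 22 cases (adjusted p = 8.21e-08, Fisher's exact test), with the synthase HMGCS1 at 10.74 ± 0.18, while the regulator SREBF2 was not above background. Housekeeping genes were detected in 16 of 17 cases (adjusted p = 6.01e-06, Fisher's exact test), with ACTB at 13.72 ± 0.18 and B2M, the light chain of MHC class I, at 11.93 ± 0.68, while ALAS1 passed on array 3 only.

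Genes of stress and signalling programmes were detected to differing degrees, and detection does not show that a programme was active. Heat shock and unfolded protein response genes were detected in 24 of 25 cases (adjusted p = 6.71e-09, Fisher's exact test), with HSPA5 at a log2 signal of 8.02 ± 0.53, HSPA8 at 12.25 ± 0.28 and HSP90AA1 at 12.91 ± 0.32 (n = 3), while CHAC1 was not above background. Actin cytoskeleton and YAP target genes were detected in 22 of 26 cases (adjusted p = 4.40e-06, Fisher's exact test), with CCN2 at 11.83 ± 0.31, CCN1 at 11.18 ± 0.06 and ANKRD1 at 6.11 ± 0.73. Among genes with a single probe this list did not pass (adjusted p = 0.0561, Fisher's exact test). Targets of p53 were detected in 13 of 21 cases (adjusted p = 0.0467, Fisher's exact test), with the cell cycle inhibitor CDKN1A at 11.41 ± 0.04 and BAX at 9.11 ± 0.34, while MDM2 was above background on array 1 only. Immediate early genes were detected in 15 of 25 cases (adjusted p = 0.0445, Fisher's exact test), with JUN at 9.44 ± 0.29 and EGR1 at 6.51 ± 0.47, while FOS was not above background. Against protein-coding genes alone, neither p53 targets (adjusted p = 0.291, Fisher's exact test) nor immediate early genes (adjusted p = 0.258, Fisher's exact test) passed. Targets of p53 also did not pass among genes with a single probe (adjusted p = 0.508, Fisher's exact test), nor immediate early genes on at least 2 arrays (adjusted p = 0.0759, Fisher's exact test) or on array 1 alone (adjusted p = 0.0755, Fisher's exact test).

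Of genes that mark retinal pigment epithelium, 7 of 24 were detected, a share that did not differ from other genes by the test (adjusted p = 0.528, Fisher's exact test). The visual cycle genes RPE65 and RLBP1 and the chloride channel gene BEST1 were not above background on any array. The detected members were the eye transcription factors OTX2 at a log2 signal of 5.97 ± 0.50 and PAX6 at 7.02 ± 0.23, the phagocytosis receptor MERTK at 7.08 ± 0.19, CDH3 at 5.60 ± 0.31, the retinol dehydrogenases RDH5 at 7.53 ± 0.23 and RDH11 at 10.42 ± 0.30, and GPNMB at 9.34 ± 0.15 (n = 3). Mesenchymal and extracellular matrix genes were detected in 24 of 39 cases (adjusted p = 0.00559, Fisher's exact test), with the intermediate filament VIM at 13.60 ± 0.30, FN1 at 6.14 ± 0.44 and the cadherin CDH2 at 10.75 ± 0.58. This list did not pass against protein-coding genes alone (adjusted p = 0.122, Fisher's exact test). Epithelial junction and keratin genes were detected in 13 of 27 cases and did not pass (adjusted p = 0.331, Fisher's exact test). In that list KRT8 had a log2 signal of 8.12 ± 0.27 and EPCAM 8.04 ± 1.38, while CDH1 was above background on arrays 2 and 3 only.

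In the fixed lists, markers of other cell types were mostly not detected. None of 24 photoreceptor genes (adjusted p = 3.28e-05, Fisher's exact test), 26 pluripotency and germ cell genes (adjusted p = 1.33e-05, Fisher's exact test) or 371 olfactory receptor genes (adjusted p = 2.60e-76, Fisher's exact test) was detected in all 3 arrays, among them CRX, NRL, POU5F1, NANOG, SOX2, OR51B4, OR1A1 and OR2W3. Striated muscle genes were detected in 1 of 31 cases (adjusted p = 3.22e-05, Fisher's exact test), MYF6 at a log2 signal of 5.36 ± 0.24 (n = 3), while MYH7, MYOD1 and CKM were not above background. Hepatocyte genes were detected in 2 of 28 cases (adjusted p = 0.000532, Fisher's exact test), FGA at 6.03 ± 0.23 and CPS1 at 7.31 ± 0.38, while ALB, APOA1 and CYP3A4 were not above background. Epidermal keratinisation genes were detected in 1 of 25 cases (adjusted p = 0.000389, Fisher's exact test), KRT10 at 9.19 ± 0.21, while KRT5, KRT14 and KRT1 were not above background. Erythroid genes were detected in 1 of 23 cases (adjusted p = 0.000552, Fisher's exact test), the embryonic globin gene HBE1 at 7.39 ± 0.95, while HBB and ALAS2 were not above background.

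Homeobox cluster genes were detected in 5 of 39 cases (adjusted p = 0.00111, Fisher's exact test), including HOXB7, a trunk patterning factor, at log2 signals of 5.06, 6.72 and 6.86 on arrays 1, 2 and 3, while HOXC10 was not above background and HOXA9 passed on arrays 2 and 3 only. The homeobox list no longer passed without replicate 1 (adjusted p = 0.054, Fisher's exact test) or among genes with a single probe (adjusted p = 0.0976, Fisher's exact test). Neuronal genes were detected in 6 of 26 cases (adjusted p = 0.166, Fisher's exact test), with SNAP25 at 5.68 ± 0.51 and TUBB3 at 8.75 ± 0.59, while SYN1 was not above background. Leukocyte genes were detected in 6 of 30 cases (adjusted p = 0.0655, Fisher's exact test), while PTPRC and CD3E were not above background. Of 49 measured genes of a B-lineage list written later, 42 were above background on any array and 24 on array 1. Over all 24793 genes these counts were 11215 and 10295. The leukocyte list passed as lower than other genes on array 1 alone (adjusted p = 0.0188, Fisher's exact test), without replicate 2 (adjusted p = 0.0446, Fisher's exact test) and without replicate 3 (adjusted p = 0.0451, Fisher's exact test). It also passed at a detection p under 0.001 (adjusted p = 0.0183, Fisher's exact test), without olfactory receptors (adjusted p = 0.0463, Fisher's exact test) and against protein-coding genes alone (adjusted p = 0.00378, Fisher's exact test). Against protein-coding genes alone, neuronal genes also passed as lower (adjusted p = 0.021, Fisher's exact test). Interferon response genes were detected in 22 of 27 cases (adjusted p = 1.60e-05, Fisher's exact test), with ISG15 at 8.73 ± 1.08, IFIT1 at 6.86 ± 0.13 and MX1 at 10.25 ± 1.62. In all, 20 lists had a higher and 9 a lower detected share than other genes and 5 did not pass. On array 1 alone, an alternative added after the data were seen, 19 were higher and 10 lower.

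**Figure D1:**
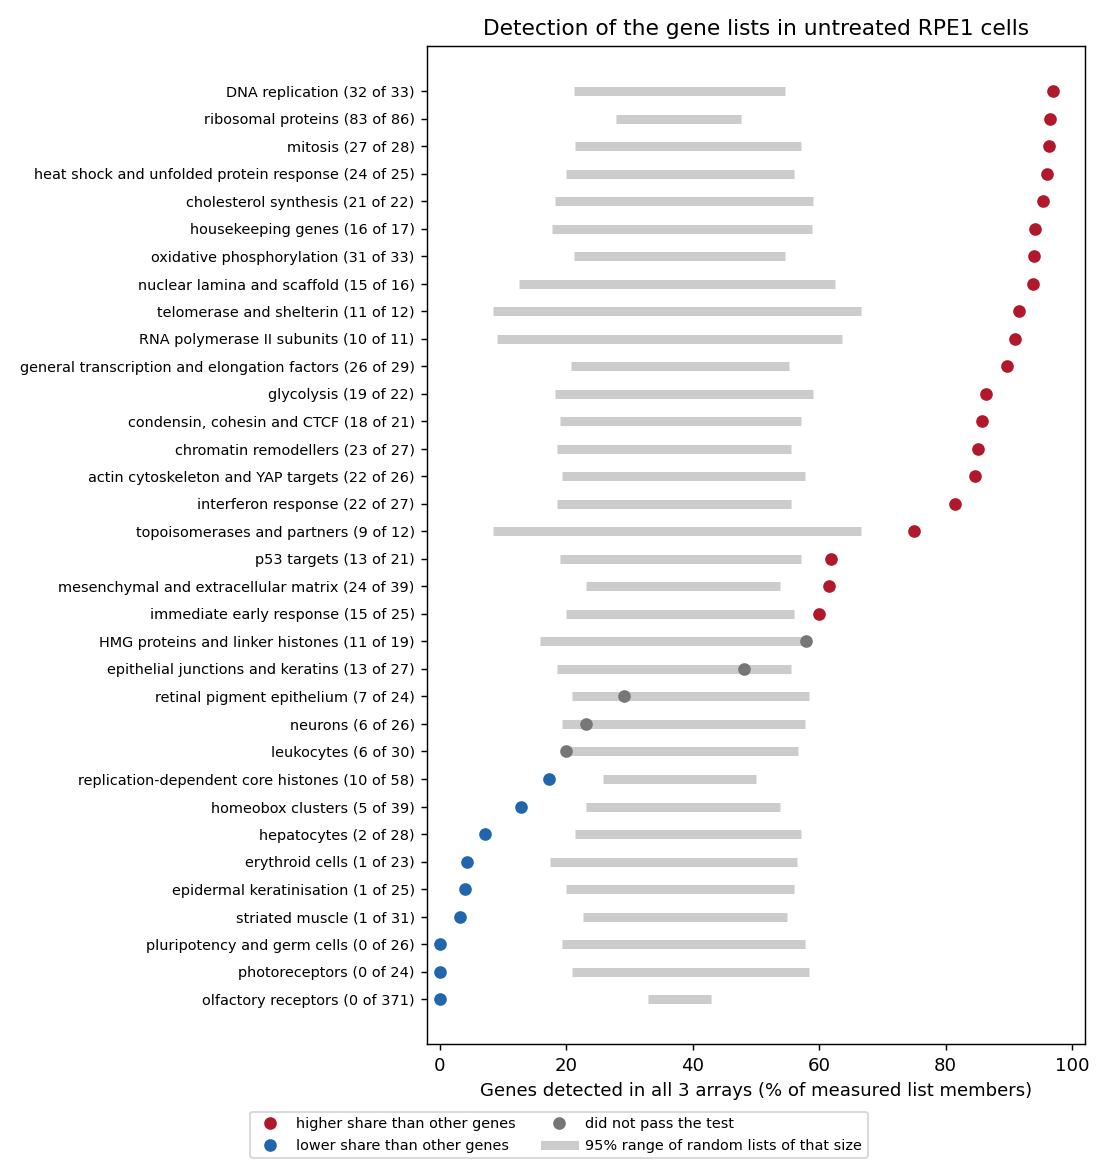
Share of each gene list's measured members detected in all 3 arrays (x axis, percent), with the number detected beside each list's name. Points are red for a higher share, blue for a lower share and grey where Fisher's exact test was not passed, and grey bars span the central 95% of 10000 random lists of the same size.

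The 3 arrays differed most in genes of B cells and MHC class II and in interferon-induced genes. HLA-DRA, an MHC class II chain, had log2 signals of 8.37 on array 1, 11.46 on array 2 and 11.97 on array 3. CD74, the class II invariant chain, had 7.56, 10.57 and 10.89, and the B-cell receptor component CD79A 6.15, 8.94 and 9.27. All 25 genes with the largest SD between replicates were lowest on array 1, by 2.68 to 3.88 against array 2 and 2.73 to 4.34 against array 3. They had SDs of at least 1.70 (n = 3), against a median of 0.201 and a 90th percentile of 0.457 over the 12055 probes detected on all 3 arrays.

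Besides HLA-DRA, CD74 and CD79A, the 25 included the class II genes HLA-DPA1 (SD 2.26) and HLA-DMB (1.73) and the predicted immunoglobulin-like genes LOC652493 (2.35) and LOC647450 (1.70). Genes of blood cell signalling and cytoskeleton among them were PLAC8 (2.14), LCP1 (2.07), ITGB7 (2.04), SLAMF1 (1.89), MAP4K1 (1.88), PTPN6 (1.80), HCLS1 (1.79), TNFRSF13B (1.78) and CYBA (1.74). The cytokine genes EBI3 (2.09) and LTA (1.74), the cyclin CCND2 (1.86), the interferon-induced nuclease ISG20 (1.72), CRIP1 (1.80) and CHCHD10 (1.97) were also among them. Of 751 genes with an SD over 0.5, 415 were lowest and 331 highest on array 1.

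By list, 7 of 27 had a larger median SD than random lists of equal signal. The leukocyte list had a median SD of 1.29, 6.38 times that of random lists (adjusted p = 0.0027, permutation over random lists), and its 6 detected members had median deviations from their mean of -1.39 on array 1 and 0.24 on array 2, with the highest on array 3. Among its members, NCF1 had log2 signals of 5.53, 7.13 and 7.75 and CD79B 6.41, 8.07 and 9.28, while the macrophage genes CD68 (9.19, 9.06 and 8.47) and CSF1R (5.46, 5.42 and 5.16) did not share that order. The interferon list had a median SD of 0.671, 3.36 times that of random lists (adjusted p = 0.0027, permutation over random lists), with median deviations of -0.68, 0.20 and 0.54. In it MX1 had log2 signals of 8.37, 11.07 and 11.30 and ISG15 7.48, 9.36 and 9.34, whereas IFIT1 had 6.98, 6.73 and 6.89. The interferon list did not pass without normalization between arrays (adjusted p = 0.138, permutation over random lists), nor the leukocyte list without a detection filter (adjusted p = 0.158, permutation over random lists).

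Other lists also varied, several of them higher on array 1, where the B-cell and class II genes were lowest. Mesenchymal and extracellular matrix genes had a median SD of 0.367 (adjusted p = 0.0054, permutation over random lists) with median deviations of 0.21, -0.08 and -0.19, as in SPARC at 9.05, 7.39 and 7.30 and CDH2 at 11.35, 10.69 and 10.19. Mitosis genes had a median SD of 0.318 (adjusted p = 0.0189, permutation over random lists) with median deviations of 0.35, -0.20 and -0.14, and DNA replication genes 0.293 (adjusted p = 0.0216, permutation over random lists) with 0.28, -0.25 and -0.03. Actin cytoskeleton and YAP target genes had a median SD of 0.289 (adjusted p = 0.0247, permutation over random lists) with median deviations of 0.28, -0.09 and -0.15. Heat shock genes had a median SD of 0.283 (adjusted p = 0.0247, permutation over random lists) with median deviations of 0.16, -0.05 and -0.04. Their median difference passed for array 2 minus array 1 (-0.25, adjusted p = 0.00967, permutation over random lists). For array 3 minus array 1 it did not (-0.21, adjusted p = 0.0589, permutation over random lists). Members were split, with 11 of 24 higher on array 2 than on array 1 and 10 of 24 higher on array 3 than on array 1. Without a detection filter the mesenchymal (adjusted p = 0.196, permutation over random lists), DNA replication (adjusted p = 0.0663, permutation over random lists), actin (adjusted p = 0.0663, permutation over random lists) and heat shock lists (adjusted p = 0.121, permutation over random lists) did not pass. The mesenchymal list also did not pass without normalization between arrays (adjusted p = 0.131, permutation over random lists), nor the DNA replication list on the authors' lumi values (adjusted p = 0.0501, permutation over random lists). Without background correction the DNA replication (adjusted p = 0.0872, permutation over random lists) and actin lists (adjusted p = 0.0531, permutation over random lists) did not pass, and among the brighter detected probes neither did the actin (adjusted p = 0.12, permutation over random lists) and heat shock lists (adjusted p = 0.0537, permutation over random lists). Across probes detected on all 3 arrays, Pearson's r was 0.960 between arrays 1 and 2, 0.951 between 1 and 3 and 0.990 between 2 and 3. Signals more than 2-fold apart were seen for 4.60%, 5.78% and 0.166% of these probes. Probes are not independent replicates, and the 3 arrays were counted as separate samples because the labels give them as such. Without replicate 1, only the leukocyte list remained past the test and the median SD of probes was 0.103. Without replicate 2 only the leukocyte and interferon lists passed, and without replicate 3 there were 9 lists, 8 with a larger and 1 with a smaller SD than random lists.

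**Figure D2:**
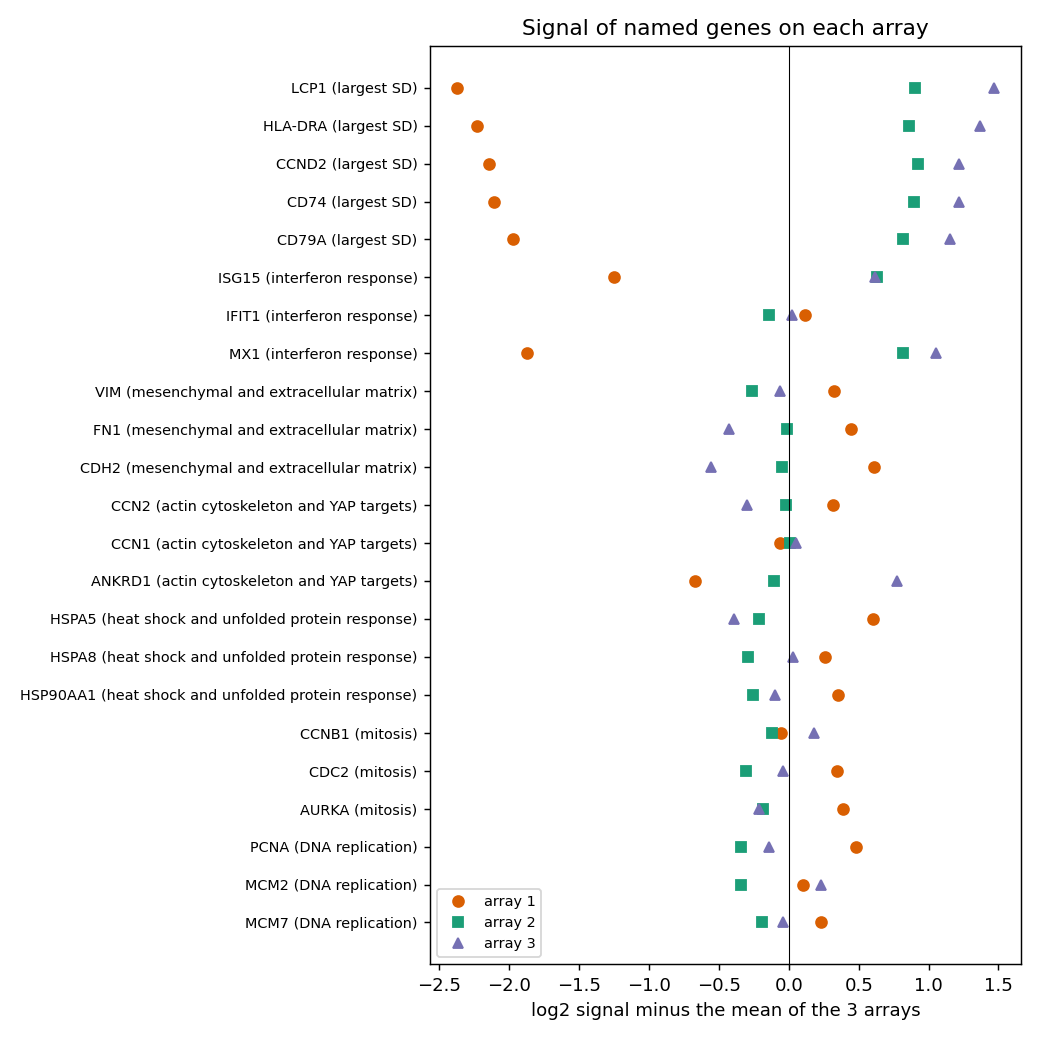
Log2 signal of each named gene on each array minus its mean over the 3 arrays (x axis), for 5 of the genes with the largest SD between replicates and detected named genes of lists with larger spread. Circles are array 1, squares array 2 and triangles array 3.

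By chromosome, the detected share was highest on chromosomes 16 (448 of 942 genes, 47.6%) and 14 (306 of 653, 46.9%) and lowest on chromosome X (313 of 970, 32.3%), against 41.1% over all placed genes. Chromosome 3 had 44.7% and chromosome 19 37.4%. These 5 passed a two-sided permutation test (adjusted p = 0.00092, 0.016, 0.00046, 0.0412 and 0.016 in that order). That test treats genes as independent. Neighbouring genes were alike in detection more often than permuted calls, so the p-values of all chromosomes may be too small. Of the 10 alternatives tried, chromosomes 16 and X passed in all 10, chromosome 19 in 7, chromosome 14 in 6 and chromosome 3 in 3. Chromosome 21 (34.6%) did not pass (adjusted p = 0.0818, permutation test) but passed as lower in 3 alternatives: on at least 2 arrays (adjusted p = 0.0458, permutation test), on array 1 alone (adjusted p = 0.0432, permutation test) and among genes with a single probe (39 of 195, adjusted p = 0.000153, permutation test), where it had the lowest share. Without replicate 1 neither chromosome 3 (adjusted p = 0.0551, permutation test) nor chromosome 19 (adjusted p = 0.054, permutation test) passed, and without replicate 3 chromosome 3 did not (adjusted p = 0.0565, permutation test). On array 1 alone 7 chromosomes passed. Among protein-coding genes only, chromosome 21 was not lower to any extent that passed, with 47.2% detected against 47.7% over all chromosomes. Chromosomes 14 and 3 did not pass there either (adjusted p = 0.13 for each, permutation test).

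Chromosome 11, along which related work mapped DNA supercoiling, had 528 of 1387 genes detected (38.1%), a difference of -2.98 percentage points that did not pass (adjusted p = 0.0771, permutation test). It passed as lower in 6 of the 10 alternatives, among them without replicate 1 (39.2%, adjusted p = 0.0429, permutation test) and without replicate 2 (39.1%, adjusted p = 0.0318, permutation test). The sign turned once olfactory receptors, many of which lie on this chromosome, were left out, with 43.2% detected against 41.7% over all genes left (adjusted p = 0.545, permutation test).

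**Figure D3:**
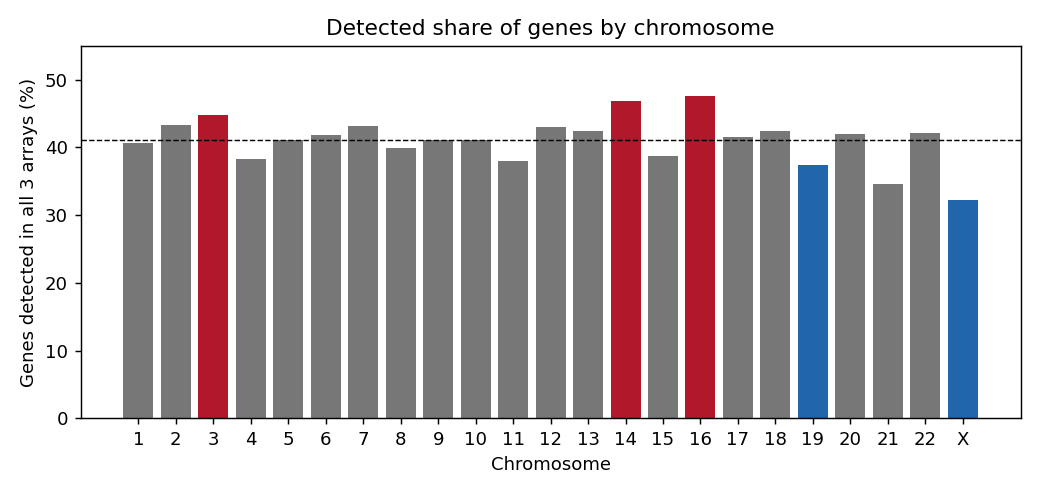
Share of genes detected in all 3 arrays (y axis, percent) on each chromosome (x axis), with a dashed line at the share over all genes assigned to these chromosomes, 41.1%. Red bars were higher and blue bars lower in the permutation test, and grey bars did not pass.

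Neighbouring genes were alike in detection more often than permuted calls. Of 19609 pairs of adjacent genes, 56.6% were both detected or both not, against a mean of 50.6% and a range of 49.5% to 51.6% over 1000 permutations of the calls within chromosomes (p = 0.0020, two-sided permutation test, the smallest these permutations can give). On chromosome 11 the share was 62.6% of 1274 pairs, against a permuted mean of 51.8% and a range of 46.8% to 56.5% over 10000 permutations (p = 0.0002, two-sided permutation test, the smallest these permutations can give). Olfactory receptors, none of them detected in all 3 arrays, are many on this chromosome. Its 1387 genes in the test by chromosome, which include some with no place in the gene order, fell to 1221 without them. The share without them was not computed for chromosome 11 by itself, so its excess may rest largely on them. Over all chromosomes the share fell with distance, from 56.6% for adjacent genes to 53.6% for genes 3 places apart and 51.7% for genes 10 places apart. On array 1 alone it was 56.3% of adjacent pairs. Leaving out olfactory receptors and neighbours that share a symbol root lowered it to 53.4%, against a permuted mean of 50.1%.

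The longest run of adjacent detected genes held 15 genes on chromosome 9, from URM1, a ubiquitin-like protein gene, at a log2 signal of 9.27 ± 0.06 to the volume-regulated channel gene LRRC8A at 7.30 ± 0.27 (n = 3). The longest run in 200 permutations had a median of 12 genes and a maximum of 20, so this run was within the permuted range. On chromosome 11 the longest run held 9 genes, from UNC93B1 at 5.82 ± 0.15 to PPP6R3 at 8.05, 7.98 and 7.96 on arrays 1, 2 and 3, against a permuted median of 7 and a maximum of 13. The longest runs of genes detected in no array were 19 genes on chromosome 1 from OR2T8 to OR2T1, of which 17 were on the olfactory receptor list, and 16 on chromosome 11 from OR5J2 to OR5AP2, all olfactory receptors. Both exceeded the longest of 13 genes seen in 200 permutations of each.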

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

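The lists of B-lineage, T-cell, myeloid, epithelial and erythroid genes, the tests on them, and the tests of neighbouring genes on array 1 alone were chosen after the differences between arrays had been seen, though before the values those tests measure. The tests on members above background on array 1 were chosen after the results on whole lists were seen. The tests of neighbouring genes without gene families and with single probes were read only after their values were known.

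Outside the named genes, 266 of 12646 probes with no gene symbol (2.10%) were above background on all 3 arrays, against 32.6% of probes with a symbol, and this signal enters no comparison.

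Many genes of B cells and of MHC class II, such as CD79A (6.15, 8.94 and 9.27 on arrays 1, 2 and 3) and CD74 (7.56, 10.57 and 10.89), were lowest on array 1. A candidate explanation is RNA of B-lineage cells in the labelled samples, more of it in those for arrays 2 and 3. A list of such genes, none of them in a fixed list or among the 25 of largest SD, was written before its values were seen. Of 49 measured members, 42 were above background on any array, and 32 of these were over 1 log2 higher on arrays 2 and 3 than on array 1. The medians were 1.64 and 1.99 (1.06 and 1.25 on the authors' lumi values), beyond all 10000 random lists of equal signal. Among the 24 members above background on array 1 the medians were 1.88 and 2.29. By contrast, 2 of 27 T-cell genes were above background on any array, and 5 detected myeloid genes had medians of 0.12 and 0.46. The members with the brightest probes were ARHGDIB at 9.86, 11.26 and 11.96, LYN at 8.91, 9.42 and 9.62, CD70 at 8.63, 9.62 and 9.57, RAC2 at 7.62, 9.75 and 10.21 and HLA-DMA at 7.32, 9.50 and 10.06, of which LYN and CD70 differed by under 1 log2. Of genes that B cells carry, however, PTPRC passed on no array and MS4A1 on array 3 only. The list members PAX5, BLNK and CD27 lay near background on every array. The B-lineage median exceeded that of the interferon list by 0.77 or more on the neqc values. On the authors' lumi values the interferon medians were 0.66 and 0.99, nearer the B-lineage medians of 1.06 and 1.25. This argues against an interferon response of the RPE1 cells alone only for genes that interferon does not itself induce. Members of the B-lineage list were not screened for such induction. Normalization is argued against, since the B-lineage median was 0.91 higher on array 2 in unnormalized log2 signal. The step at which such RNA might have entered, and expression of these genes by RPE1 cells themselves, stay open. The 25 genes of largest SD had standard errors over beads of 0.127 to 0.251 log2, averaged over the arrays. The median over probes detected on all 3 arrays was 0.0775. Those genes were picked for their spread, and whether signal was uneven within an array was not tested. Apart from the interferon response no biological explanation was tested because the design has 1 group.

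EPCAM (6.45, 8.74 and 8.94), KRT19 (7.32, 9.01 and 9.70) and CLDN7 (not above background on array 1, 6.79 on array 2 and 6.95 on array 3) followed the same order. RNA of epithelial carcinoma cells is a candidate that met the test set beforehand. Of 32 measured members of a further list, 13 were above background on any array, a filter that can admit members through arrays 2 and 3. Of these 13, 8 were higher on arrays 2 and 3, with medians of 0.64 and 0.56 (adjusted p = 0.000543 and 0.0038, permutation over random lists). Over 1 log2 on both were 4 members, including SPINT2 (7.15, 8.62 and 8.63), SFN (5.36, 6.67 and 6.86) and LAD1 (5.88, 7.43 and 7.47). The list also passed on the authors' lumi values with smaller medians of 0.39 and 0.29 (adjusted p = 0.000543 and 0.00675, permutation over random lists), and on unnormalized signal with 0.18 and 0.16 against random medians of -0.28 and -0.31 (adjusted p = 0.000543 and 0.00217, permutation over random lists). Among the 9 members above background on array 1 the medians were -0.56 and -0.20, against random medians of -0.16 and -0.19. The first passed in the opposite direction (adjusted p = 0.0244, permutation over random lists) and the second did not pass (adjusted p = 0.958, permutation over random lists). KRT80 was highest on array 1 (10.28, 9.63 and 9.57) and KRT18 had 6.42, 6.44 and 6.57. The epithelial regulators ESRP1, GRHL2 and ELF3 were not above background, so this source stays open. Whether these genes came with the B-lineage genes or from a separate source was not tested, and no biological explanation was tested.

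Neighbouring genes were alike in detection 5.95 percentage points more often than permuted calls. Families of similar genes lying side by side are argued against as the whole cause, since 3.27 points remained without olfactory receptors and neighbours of shared symbol root. Unequal numbers of probes per gene are argued against likewise, since the excess was 5.06 points among genes with a single probe. The excess was 6.14 points on array 1 alone, so it did not depend on arrays 2 and 3. RNA of other cells is not excluded by this, since 24 of 49 measured B-lineage genes were above background on array 1 too. Neighbours were not tested among protein-coding genes alone, of which 47.7% were detected against 37.9% of all genes, so gene class stays open. Overlapping transcripts of neighbours and shared regulation of neighbours stay open too, and no biological explanation was tested because the design has 1 group.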

How the results depend on the processing

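No paired analysis was possible because the labels give 1 group only. The tests on array 1 alone, against protein-coding genes only and by permutation of neighbours were chosen after the data were seen, the last on simulated data only. The count of detected genes lay between 7468 and 11140 under other thresholds, array subsets and array numbers, and was 5629 among single-probe genes, where fewer genes are tested. Between 26 and 30 of 34 gene lists passed under each alternative for detection, and no called list changed direction. The excess of alike neighbours lay between 3.27 and 6.25 percentage points and exceeded the permuted calls in each alternative run. For chromosomes, 3 passed at a detection p under 0.05, under 0.001 and among single-probe genes; the cause was not tested. Chromosome 11 passed as lower at a detection p under 0.05 (43.98%), on at least 2 arrays (40.7%), on array 1 alone (41.5%), among protein-coding genes (41.6%) and, leaving out each replicate in turn (38.5% to 39.2%), in 2 of 3 cases. The median SD was 0.125 without background correction and with 50 added to the signal, 0.162 with neither correction nor addition, 0.374 without normalization between arrays, 0.104 without a detection filter and 0.103 to 0.211 leaving out each replicate, the lowest without replicate 1. Of the lists varying between replicates, 2 passed without a detection filter, 4 among the brighter detected probes and 1 to 9 leaving out each replicate; the cause was not tested. The interferon list's spread did not pass without normalization between arrays (adjusted p = 0.138, permutation over random lists) and the leukocyte list's without a detection filter (adjusted p = 0.158, permutation over random lists). The circular shifts planned for neighbours gave p = 0.819 (two-sided permutation by shifts) and are void. Gene density and its windows, and neighbours at least 100 kb apart, were not run. Signal over background limits detection, since 26.4% to 28.7% of probes passed on each array.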

Other observations

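The tests on the erythroid list and on pairs of probes were chosen after the differences between arrays had been seen.

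Genes of several other programmes also differed between the arrays. The actin regulator list had median differences of -0.40 for array 2 minus array 1 and -0.40 for array 3 minus array 1, and cholesterol synthesis genes -0.26 and -0.41, while ribosomal protein genes had 0.17 and 0.19, with 64 and 59 of 83 detected members higher. These lists each lay beyond most of the 10000 random lists of equal signal (adjusted p = 0.000543, 0.0161 and 0.00304 for array 2 minus array 1, permutation over random lists), as a description of these arrays only. On the authors' lumi values cholesterol synthesis did not pass for that pair (adjusted p = 0.0697, permutation over random lists). In the test of SD between replicates, neither ribosomal protein nor cholesterol synthesis genes passed. Ribosomal protein genes had a median SD of 0.152 against 0.179 for random lists (adjusted p = 0.236, permutation over random lists). Cholesterol synthesis genes had 0.239 against 0.189 (adjusted p = 0.289, permutation over random lists). Within the mesenchymal list, S100A4 went against the median at 8.25, 9.61 and 9.79.

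HBE1, an embryonic globin gene, had log2 signals of 6.29, 7.98 and 7.91 on arrays 1, 2 and 3, and GYPC, a red cell membrane gene, 5.10, 6.68 and 6.64. Of a list of 22 erythroid genes, 7 of them also in the fixed lists, 6 were above background on any array, with medians of 0.35 and 0.46 for arrays 2 and 3 minus array 1 that did not pass (adjusted p = 0.0932 and 0.0722, permutation over random lists). On the authors' lumi values array 3 minus array 1 passed, with a median of 0.32 (adjusted p = 0.0347, permutation over random lists). HOXB7 had 5.06, 6.72 and 6.86.

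For 2005 genes with at least 2 detected probes, the differences of array 3 minus array 1 correlated across genes with Pearson's r of 0.674, genes not being independent replicates. Where the first probe differed by over 1 log2, the second had the same sign in 91.0% of genes. Some genes passed on part of the arrays only: 447 on array 1 only, 58 on array 2 only, 498 on array 3 only, 364 on arrays 2 and 3 but not 1, 339 on arrays 1 and 3 but not 2, and 98 on arrays 1 and 2 but not 3.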
